A study of Mus musculus with 8 samples.

How the data were processed

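RNA was sequenced from spleen CD4 T cells after 2 days of pathogenic Th17 differentiation, in 4 libraries labelled wild type and 4 labelled Cyp1b1 knockout. Per the labels' protocols, polyadenylated RNA was captured on oligo-dT beads, fragmented, and copied with random hexamer primers, with no strand-marking step named. It is therefore not known whether reads of overlapping or antisense genes were told apart.

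The authors deposited a table of raw counts per gene for all 8 libraries, with Ensembl identifiers, symbols, positions and biotypes. Its values are whole numbers whose totals differ between libraries, and no normalization had been applied. Per the submitters' processing notes, fastp was used (version not stated), which trims and filters reads. The aligner, the counter, the annotation and whether counting used strand are not given in the sources used here. No genome build is named either: 54495 of 54532 gene identifiers were found in the GENCODE M21 annotation of GRCm38, 53585 with the same start and end, so positions are given as GRCm38. Counting affects what can be read from the table: reads shared by near-identical copies, such as Gapdh and ribosomal protein pseudogenes or nuclear copies of mitochondrial genes, may be split or dropped, and counts per gene do not show exons. Where a symbol had more than 1 row, the row with the larger count was used for gene lists.

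Total counts ran from 8918342 to 15667313 per library. Reads carry no molecular identifiers, and precision was judged from the spread between replicates. Counts of replicates within a label differed by more than sampling noise in all pairs (chi-square per gene from 3.69 to 12.3 over genes with at least 20 counts), so each library counted once.

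Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15), which left 14428 of 54532. Libraries were scaled by TMM, and a quasi-likelihood F-test with robust dispersion compared genotypes in a model with genotype alone, two-sided, with Benjamini-Hochberg adjustment. Adjusted p under 0.05 was called. CPM values of genes are TMM-scaled per library, summed CPM of marker lists and shares of counts use library totals, and log2 CPM for principal components used a prior count of 2. Standard errors of log2 fold changes were taken as the fold change over the square root of F. The common biological coefficient of variation was 0.0895.

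Before the data were examined, 41 gene lists were fixed on T helper programs, redox, mitochondria, metabolism, stress, proliferation, marker genes of other cell types and technical signals. The 40 with at least 3 tested members were tested by camera with a preset inter-gene correlation of 0.01, and with an estimated correlation and fry as alternatives. Also fixed then was the rule for the genes named: Cyp1b1, Il17a, Il17f, Csf2, Il23r, Foxp3, Ahr and Nfe2l2 always; the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and libraries that do not overlap between labels, leaving out predicted or clone names, pseudogenes and receptor segments; and from each list up to 3 called members with the smallest p, or 2 members where none was called. Some genes the rule names are not reported here. Library measures, such as shares of counts and summed marker CPM, were compared by exact permutation over 70 assignments. Called genes within 20 Mb of Cyp1b1 were compared with the rest of the genome by Fisher's exact test, leaving out Cyp1b1.

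For the check of their trend, GC content came from the longest GENCODE M21 transcript of each gene and gene length from the deposited table. Values were at hand for 14415 of 14428 genes.

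The steps were tested on counts simulated for 14428 genes from the means, library sizes and dispersions of this comparison, with known changes. Of 67 genes changed by 1.5-fold, 68.7% were recovered, of 66 changed by 2-fold 89.4%, and of 64 changed by 4-fold all. False calls made up 4.41% of 204. Far fewer genes were changed there than the 4380 called in the data, and those given these folds had a mean above 1 CPM. These rates therefore need not carry over to the comparison itself. Genes that failed the filter, which left 14175, were not counted.

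Alternatives fixed at the same time as the lists were DESeq2 size factors in edgeR, library totals alone, no low-count filter, CPM of at least 1 in 4 libraries, replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom, protein-coding genes alone, other windows around Cyp1b1, and other list tests. Those added after the data were seen were knockout replicates 1 and 4 or 2 and 3 alone, a term for the split of samples within genotype, the B cell marker level as a covariate, and the fold limit of 2 near Cyp1b1. The B cell marker level is the log2 summed CPM of the markers. Its most abundant member, Ighm, hardly differed between labels (345.9 and 342.5 CPM), so the covariate follows the fall of the markers poorly. Calls gained or lost with it cannot be read as adjusted for residual B cells.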

Results

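The study measured gene expression by RNA sequencing in CD4 T cells from mouse spleen after 2 days of culture under conditions that drive them toward pathogenic Th17 cells, the interleukin-17 producing helper cells linked to autoimmune inflammation. The series title puts the question as the part that cytochrome P450 1B1, encoded by Cyp1b1, plays in forming these cells, in their redox balance and in their mitochondria. Of 8 libraries, 4 were labelled wild type and 4 were labelled Cyp1b1 knockout. Total counts were 13937896, 8918342, 14110402 and 14335944 in wild type replicates 1 to 4, and 14542139, 14635546, 13271968 and 15667313 in knockout replicates 1 to 4. The labels do not say whether replicates came from separate animals or cultures, so p-values measured only the spread between these libraries, which may be technical.

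Cyp1b1 itself was 41.8-fold higher in the libraries labelled knockout, against the direction that the label would lead one to look for. The gene (ENSMUSG00000024087) lies on the minus strand of chromosome 17 at 79706953 to 79715041 (GRCm38 coordinates). It had 64, 34, 63 and 69 counts in wild type replicates 1 to 4, and 2179, 3169, 3007 and 2069 counts in knockout replicates 1 to 4. The mean was 4.36 ± 0.43 CPM in the libraries labelled wild type and 184.8 ± 47.9 CPM in those labelled knockout (SD, n = 4 each). The log2 fold change was 5.39 with an SE of 0.24 and an edgeR adjusted p of 9.91e-07, and the exact two-sided permutation test gave p = 0.0286, the smallest that 70 assignments allow. Gene-level counts do not show which exons the reads came from, and every direction given here therefore rests on genotype labels that the Cyp1b1 level goes against.

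**Figure D1:**
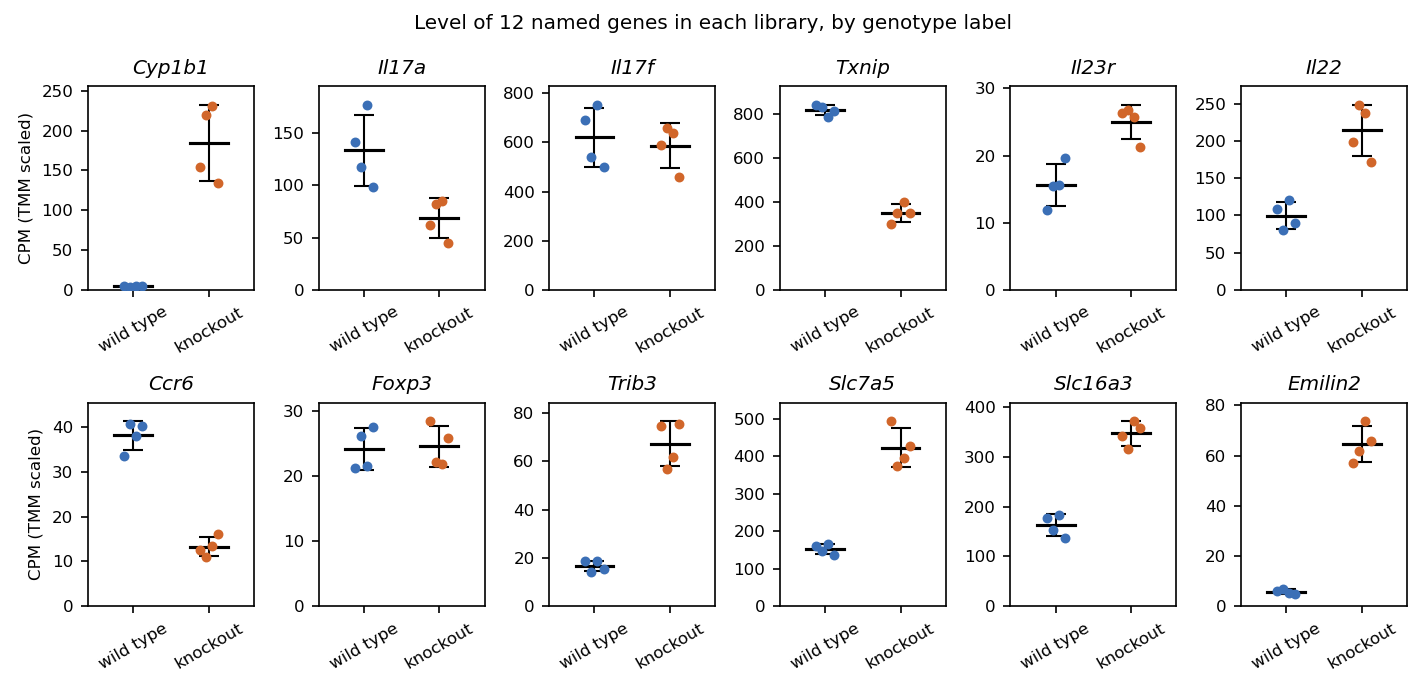
TMM-scaled CPM (y axis from 0) of 12 named genes in each of the 8 libraries, by genotype label. Points are libraries, wide bars the mean and thin bars 1 SD (n = 4 each); Cyp1b1 lay at a mean of 4.36 CPM in the libraries labelled wild type and 184.8 CPM in those labelled knockout.

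Among the largest changes, Cth, Emilin2 and Aldh1l2 rose with Cyp1b1 in the libraries labelled knockout, and Il27, Xlr3b and Fcrla fell. Cth, which makes cysteine by transsulfuration, rose from 3.87 ± 1.03 to 46.2 ± 5.42 CPM (SD, n = 4 each), a log2 fold change of 3.61 (SE 0.14). Slc7a11, the cystine importer, rose by 3.01 (SE 0.32), and Aldh1l2, a mitochondrial folate enzyme, by 3.49 (SE 0.18). Pparg, a lipid-sensing nuclear receptor, rose by 3.13, and Akr1c18, a steroid dehydrogenase, by 2.93. Emilin2, Pcdh7, Cacna1c and Uchl1 completed the 10 largest rises with Cyp1b1, at 3.496, 3.001, 2.83 and 2.76. Among the 10 largest falls, the cytokine gene Il27 changed by -3.01 and Il12a by -2.16, the B-lineage genes Fcrla, Jchain and Fcamr by -2.96, -2.90 and -2.74, and the Notch target Hes1 by -2.90. Xlr3b, Cd63 and Hdac9 fell by 2.96, 2.92 and 2.30 on the log2 scale. Low levels make the size of several folds uncertain. Slc7a11, Pparg, Pcdh7 and Uchl1 had means of 0.48, 0.38, 0.36 and 0.66 CPM in the libraries labelled wild type. Il27, Il12a, Hes1 and Fcamr had 0.34, 0.48, 0.31 and 0.31 CPM in those labelled knockout. Snord53, a small nucleolar RNA inside another gene, had -3.12, and reads of its host gene can be counted for it. Xlr3b has near-identical paralogs, so its value is uncertain as well. Snord53 and Emilin2 lie within 20 Mb of Cyp1b1 on chromosome 17, where called genes were over-represented. Each of these 20 genes had an edgeR adjusted p of 0.000202 or less, and in each the 4 libraries of one label lay above the 4 of the other, which the rule for naming them required.

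In all, 4380 of 14428 tested genes passed an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 2272 were higher and 2108 lower in the libraries labelled knockout, and 578 changed by at least 2-fold, 236 higher and 342 lower. Scaling by library totals alone turned the split to 1745 higher and 2689 lower. Libraries of the 2 labels did not overlap in 4206 tested genes, 29.2% against the 2.86% that chance gives for 4 against 4.

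**Figure D2:**
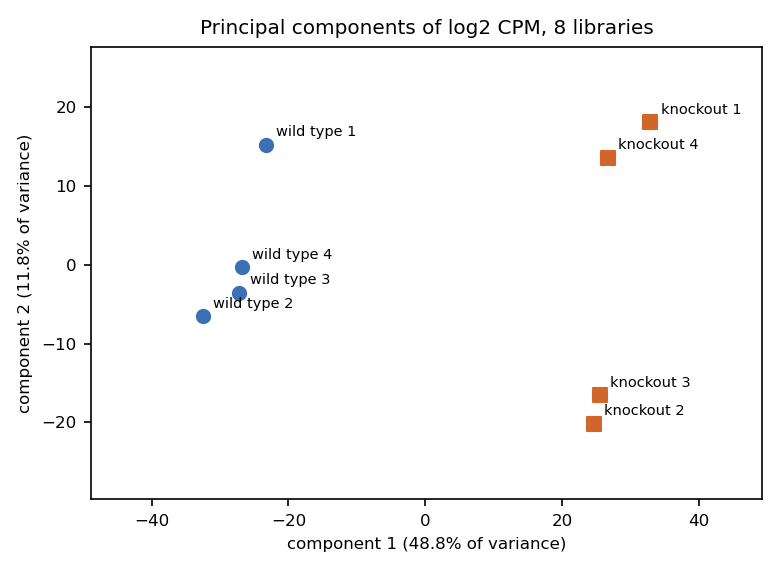
First and second principal components of log2 CPM of the 8 libraries, with the share of variance on each axis; circles are libraries labelled wild type and squares those labelled knockout. Component 1 (48.8% of variance) separates the labels and component 2 (11.8%) separates knockout replicates 1 and 4 from 2 and 3.

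Within each label the libraries were not uniform. Along the main direction of spread within labels, wild type 1 lay with knockout 1 and 4, and the other 5 libraries lay on the opposite side. With these sides as a term in the model, added after the data were seen, 4716 genes passed. The sides were drawn from these same counts, so a term for them lowers the remaining spread by construction. The larger number of calls is therefore no independent support. Some changes differed in size between the sides, with examples chosen after their values were seen. Cacna1c rose by 4.25 on the side of wild type 1 and by 2.34 on the other, and Bnip3 by 0.69 and 1.23. The first side holds only 1 library labelled wild type.

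The Th17 program changed in both directions. Ccr6, the chemokine receptor typical of Th17 cells, fell from 38.1 ± 3.23 to 13.3 ± 2.10 CPM (SD, n = 4 each) in the libraries labelled knockout, a log2 fold change of -1.52 (SE 0.11, edgeR adjusted p = 4.89e-10). Il17a, the signature cytokine, was lower at 68.7 ± 18.9 CPM against 133.6 ± 34.1 CPM, while Il22 rose from 99.6 ± 18.1 to 213.8 ± 34.9 CPM and Il23r, the receptor that sustains pathogenic Th17 cells, from 15.6 ± 3.16 to 25.04 ± 2.56 CPM. In the Th17 core list 3 members rose, 8 fell and 12 did not pass, with the same 3 and 8 when adjusted over the list alone. Other falls in it were Cxcr6 (-0.80) and Maf (-0.39). The pathogenic Th17 list had 5 higher, 6 lower and 8 not passing (6 and 8 adjusted over the list alone), with Lgals3 at 0.64 and Il7r and Icos at -0.64 and -0.55. The non-pathogenic list had 2 higher, 2 lower and 4 not passing, also when adjusted over the list alone, with Ikzf3 at 0.65 and the regulatory cytokine Il10 at -0.99. None of the 3 lists moved as a whole by camera: their median log2 fold changes were -0.092, -0.24 and -0.031, and the adjusted p values were 0.117, 0.4 and 0.818 (0.641, 0.624 and 0.877 with an estimated correlation). The core list passed as lower without wild type 4 (0.0405), with knockout 1 and 4 alone (0.0229) and with the B cell marker level as a covariate (median -0.22, 0.000428). That covariate follows the fall of the B cell markers poorly. The pathogenic list passed as lower with fry (adjusted p = 0.0323), which does not compare a list with other genes.

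Several regulators and effectors of the program did not pass. Il17f had 620.9 ± 121.1 CPM in the libraries labelled wild type and 586.5 ± 90.7 CPM in those labelled knockout, a log2 fold change of -0.083 (SE 0.17, edgeR adjusted p = 0.756). With the B cell marker level as a covariate, added after the data were seen, Il17f passed as lower at -0.43 (adjusted p = 0.000628). Because this covariate follows the fall of the markers poorly, that value cannot be read as adjusted for residual B cells. Foxp3, the regulatory T cell factor, gave 0.030 (SE 0.11), turning to -0.021 with library totals, Ahr, the aryl hydrocarbon receptor, gave 0.075 (SE 0.11) and Nfe2l2, the NRF2 gene, -0.10 (SE 0.067). Csf2, the GM-CSF gene, stood near 1 CPM in either label and did not pass (0.28, SE 0.36). The call of Il17a (log2 fold change -0.96, SE 0.27, adjusted p = 0.0406) was close to the threshold. Leaving out any 1 library except wild type 4 ended the Il17a call, with adjusted p up to 0.105, and over all alternatives the adjusted p ran from 2.39e-08 to 0.191.

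Genes of the integrated stress response, the ATF4-driven program that amino acid shortage and other stresses switch on, rose together in the libraries labelled knockout. Of 22 measured members, 20 rose, none fell and 2 did not pass (21 and 0 adjusted over the list alone). Trib3, an ATF4 target, rose from 16.7 ± 2.26 to 67.3 ± 9.41 CPM and Slc7a5, a large amino acid transporter, from 152.2 ± 13.6 to 423.5 ± 52.3 CPM (SD, n = 4 each). The median log2 fold change was 1.12, with a camera adjusted p of 4.21e-49 and an adjusted p of 0.049 with an estimated correlation. It was the only list called under an estimated correlation.

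Glycolysis and hypoxia genes rose as well. Of 31 members, 26 rose, none fell and 5 did not pass (28 and 0 adjusted over the list alone). The lactate exporter Slc16a3 rose from 162.5 ± 21.7 to 346.4 ± 24.3 CPM, and the oxygen sensor Egln1 and the pyruvate dehydrogenase kinase Pdk1 rose by 1.05 and 0.78 on the log2 scale. The list's median was 0.68 (camera adjusted p = 2.97e-27, and adjusted p = 0.114 with an estimated correlation). Gapdh, chosen after its values were seen, varied widely (69.0 ± 60.1 and 267.2 ± 230.0 CPM) and did not pass, and its reads can be shared with near-identical pseudogenes. Of 37 proliferation genes, 27 rose, none fell and 10 did not pass (30 and 0 adjusted over the list alone). Among them were Uhrf1, which keeps DNA methylation through replication, at 0.64, Tyms, which makes thymidylate, at 0.78, and Birc5, a mitotic survivin, at 0.60. The median was 0.37 (camera adjusted p = 5.64e-13, and adjusted p = 0.292 with an estimated correlation). B cell markers were lower in the same libraries, with a median of -0.86, and stood beside all 3 of these lists.

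**Figure D3:**
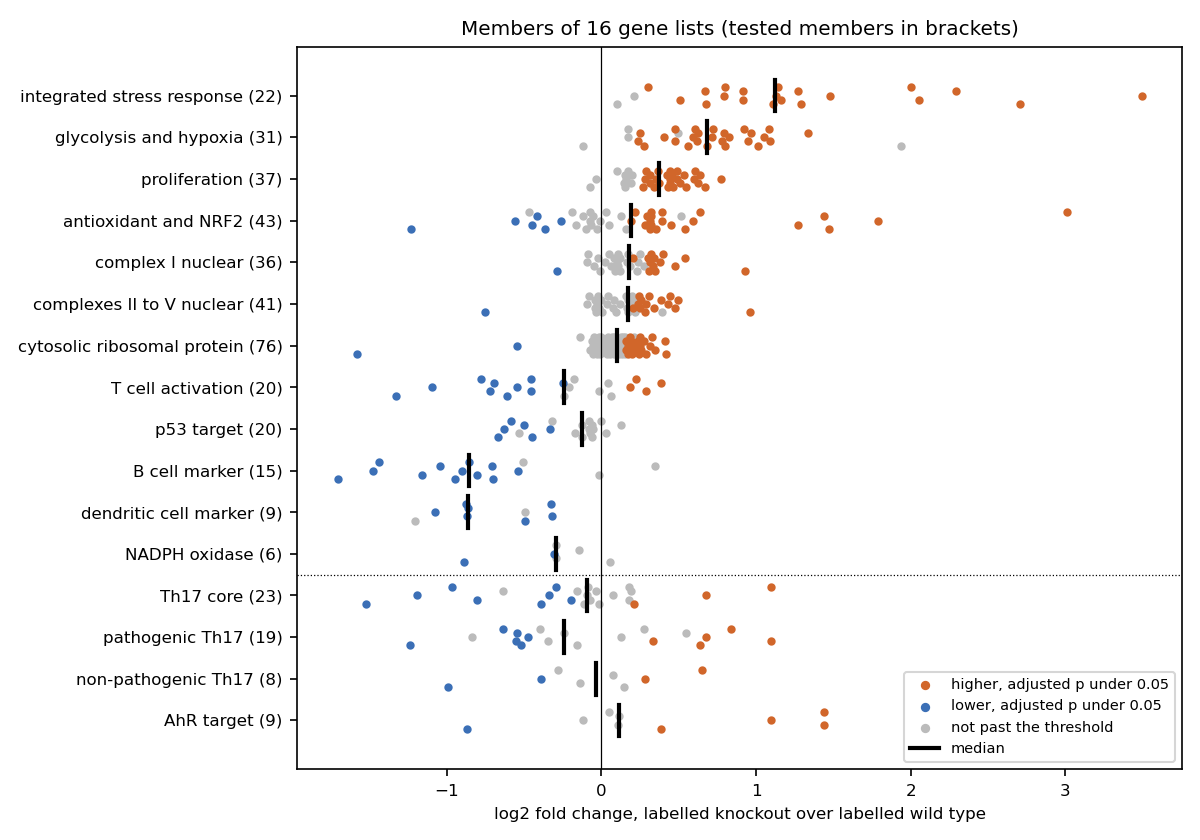
Log2 fold change (x axis, labelled knockout over labelled wild type) of each tested member of 16 gene lists; points are genes coloured by the edgeR result, and black bars are list medians. The 12 lists called by camera lie above the dotted line; integrated stress response has the largest rise (median 1.12), B cell and dendritic cell markers the largest falls (both -0.86), and the Th17 lists below the line hold genes on both sides of 0.

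Redox genes, which the series title names, changed in both directions. Of 43 antioxidant and NRF2 genes, 21 rose, 6 fell and 16 did not pass (the same 21 and 6 adjusted over the list alone). Besides Slc7a11, the heme oxygenase Hmox1 rose from 7.06 ± 1.54 to 19.3 ± 1.17 CPM, while Txnip, a thioredoxin inhibitor that also limits glucose uptake, fell from 818.6 ± 24.5 to 349.3 ± 39.7 CPM (SD, n = 4 each). The list's median was 0.20 (camera adjusted p = 0.0116, and adjusted p = 0.292 with an estimated correlation), and with knockout 2 and 3 alone its adjusted p was 0.058. Of 6 NADPH oxidase genes, none rose, 2 fell and 4 did not pass (0 and 4 adjusted over the list alone). The falls were Ncf1 at -0.89 and Ncf4 at -0.30. Their median was -0.29 (camera adjusted p = 0.0216, and adjusted p = 0.214 with an estimated correlation), and the call ended without knockout 2 (0.0568), with knockout 1 and 4 alone (0.108) and with the B cell marker level as a covariate (0.112). That covariate follows the fall of the B cell markers poorly. B cell and dendritic cell markers, with medians of -0.86, were lower in the same libraries. Of 9 AhR targets other than Cyp1b1, 4 rose, 1 fell and 4 did not pass, as also when adjusted over the list alone. Cyp1a1 rose from 7.17 ± 0.84 to 19.4 ± 1.09 CPM and Gpr15 had -0.87, a call that ended with the B cell marker level as a covariate (-0.54, adjusted p = 0.102). The list was not called (median 0.11, camera adjusted p = 0.0516, adjusted p = 0.292 with an estimated correlation). Without knockout 1, knockout 4, wild type 1 or wild type 3 it passed, at 0.036, 0.0246, 0.0498 and 0.0193, as it did with library totals (0.0388), with no low-count filter (0.0084) and with knockout 2 and 3 alone (0.0115).

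Some nuclear genes of the respiratory chain rose in the libraries labelled knockout while most did not pass, and the genes on mitochondrial DNA did not move as a list. Of 36 complex I genes, 13 rose, 1 fell and 22 did not pass (15 and 1 adjusted over the list alone), with Ndufs5 at 0.93 and Ndufa3 at 0.54. Of 41 genes of complexes II to V, 15 rose, 1 fell and 25 did not pass (20 and 1 adjusted over the list alone), with Uqcrq at 0.96 and Cox7a2l at -0.75. Cox7a2l, the 1 that fell, lies 3.79 Mb from Cyp1b1, in a stretch of chromosome 17 where called genes were over-represented. The medians were 0.18 for each list (camera adjusted p = 0.00283 and 0.0033, and adjusted p = 0.571 and 0.624 with an estimated correlation). Of 12 mitochondrially encoded genes, 1 rose and 11 did not pass (none when adjusted over the list alone). That gene was mt-Cytb at 0.39 (edgeR adjusted p = 0.0445), and 5 of 8 fits without 1 library ended its call. They were those without knockout 1, 2 or 3 or wild type 2 or 3, with adjusted p from 0.0539 to 0.143, and scaling by library totals (0.0888), either pair of knockout libraries alone (0.336 and 0.157) and the B cell covariate (0.112) also ended it. Reads of this genome can be split with nuclear copies, so its values are uncertain. Mitochondrial ribosome genes had 11 higher and 5 lower of 74 (11 and 3 adjusted over the list alone), with Mrpl54 at 0.58 and Mrps10 at -0.45. Biogenesis genes had 4 higher and 3 lower of 29 (3 and 3), with the mitochondrial protease Lonp1 at 0.77 and the coactivator Pprc1 at -0.49. For dynamics and mitophagy it was 2 and 2 of 18 (2 and 2), with Bnip3 at 1.02. TCA cycle genes had 1 higher and 2 lower of 20 (0 and 0). Fatty acid oxidation genes had 2 higher and 3 lower of 18 (2 and 3), with Acadl at -0.58. Camera adjusted p values of these 5 lists were 0.469, 0.824, 0.632, 0.825 and 0.987, and 0.825 for the mitochondrially encoded genes; with an estimated correlation the 6 ranged from 0.774 to 0.989. With no low-count filter the mitochondrial ribosome list passed as higher (0.0295).

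In the libraries labelled knockout, 10 of 20 T cell activation genes and 6 of 20 p53 targets fell, and 22 of 76 cytosolic ribosomal protein genes rose. Of 20 activation genes, 4 rose, 10 fell and 6 did not pass (4 and 12 adjusted over the list alone). Nfkbid, a nuclear regulator of NF-kB, fell from 51.9 ± 4.33 to 24.2 ± 3.62 CPM, Icos, a costimulatory receptor, from 797.5 ± 39.3 to 545.6 ± 36.8 CPM and Irf8 from 72.1 ± 2.19 to 44.6 ± 2.21 CPM (SD, n = 4 each). The median was -0.24 (camera adjusted p = 0.00283, and adjusted p = 0.114 with an estimated correlation). B cell and dendritic cell markers were lower in the same libraries, both with a median of -0.86. Of 20 p53 targets, none rose, 6 fell and 14 did not pass, as also when adjusted over the list alone. They included Trp53inp1 at -0.67 and Plk2 at -0.63, and the median was -0.12 (camera adjusted p = 0.00283, and adjusted p = 0.214 with an estimated correlation). Of 76 cytosolic ribosomal protein genes, 22 rose, 2 fell and 52 did not pass (23 and 2 adjusted over the list alone), with Rplp0 at 0.41 and Rpsa at 0.31. The median was 0.10 (camera adjusted p = 0.00886, and adjusted p = 0.674 with an estimated correlation), and the camera adjusted p was 0.0588 without wild type 2 and 0.112 with the B cell marker level as a covariate. That covariate follows the fall of the B cell markers poorly. Rpl24 had only 7.87 CPM in the libraries labelled wild type, so its fall of -1.58 is uncertain, since reads of ribosomal protein genes can be shared with processed pseudogenes.

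Markers of other spleen cell types also differed between the labels. Of 15 B cell markers, none rose, 12 fell and 3 did not pass (0 and 13 adjusted over the list alone). Cd79b, part of the B cell receptor, fell from 23.5 ± 2.97 to 12.2 ± 1.37 CPM, and Bank1 and the kinase Blk fell by 1.04 and 1.44 on the log2 scale. Ighm, the most abundant of them and chosen after its values were seen, stood at 345.9 ± 74.7 and 342.5 ± 64.8 CPM (SD, n = 4 each) and did not pass. Of 9 dendritic cell markers, none rose, 7 fell and 2 did not pass, as also when adjusted over the list alone, with Flt3 at -1.08 and the class II genes H2-Eb1 and H2-Aa at -0.88 and -0.87. B cells carry class II as well. Medians of both lists were -0.86 (camera adjusted p = 1.11e-09 and 2.18e-05, and adjusted p = 0.292 and 0.0741 with an estimated correlation). NK cell markers had 1 higher and 4 lower of 9, among them Klra7 at 1.61 and Gzma at -0.94. Myeloid markers had 1 higher and 2 lower of 7, with Ly6g at 1.43 and Cd68 at -0.90. Both counts were the same adjusted over the list alone. Klra7 and Ly6g belong to families of similar genes whose reads can be shared, and 3 of the NK genes are also in the myeloid list. Innate-like T cell markers had 1 and 1 of 3 (1 and 1 adjusted over the list alone), and Blk is shared with the B cell list. Erythroid and platelet markers had 1 and 2 of 5 (2 and 2), with a median of 0.074 and a test that pointed down, and stromal and endothelial markers 2 and 0 of 5 (2 and 0), with Pecam1 at 0.70. CD4 T cell identity genes had 5 higher and 0 lower of 14 (5 and 1), with Cd28 at 0.29. Camera adjusted p values were 0.237, 0.825, 0.178, 0.84, 0.237 and 0.178 for these 6 lists, and 0.571 or more with an estimated correlation. The CD4 identity list passed as higher with no low-count filter (0.00423) and with knockout 1 and 4 alone (0.0281). The 2 tested CD8 markers did not pass (Cd8a 0.50, Cd8b1 -0.16), though Cd8a did with knockout 1 and 4 alone (0.72, adjusted p = 0.0387) and with the B cell marker level as a covariate (0.77, adjusted p = 0.0491). That covariate follows the fall of the B cell markers poorly.

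Summed over a list and scaled by library totals, B cell markers took 673.6 ± 131.4 CPM in the libraries labelled wild type and 509.6 ± 76.0 CPM in those labelled knockout, and dendritic cell markers 447.7 and 299.8 CPM (n = 4 each). By exact two-sided permutation tests p was 0.0857 and 0.0286. In a family of 15 library measures, the sums of NK and dendritic markers, which were lower, those of innate-like, myeloid and stromal markers, and the share of counts in the 100 most abundant genes (17.5 ± 0.12% and 18.4 ± 0.15%) all reached 0.0286, the smallest exact p possible, with a Benjamini-Hochberg adjusted p of 0.0714. Single genes carried 3 of these sums: Blk, also a B cell marker, the lower innate-like sum (22.7 and 8.36 CPM), Ly6g the higher myeloid sum (11.04 and 29.92 CPM) and Pecam1 the higher stromal sum (88.1 and 142.7 CPM), so the sums give no direction for these classes. Gzma (14.1 and 7.36 CPM) gave a large part of the NK fall, while Klra7 rose (1.22 and 3.78 CPM). Cd74 (168.1 and 119.6 CPM) was the most abundant dendritic marker, followed by class II gene H2-Ab1, and B cells carry class II as well. Neither sum need reflect fewer cells of its class. Mitochondrially encoded genes took 1.78 ± 0.32% and 1.58 ± 0.22% of counts (exact p = 0.286, adjusted 0.357), and ribosomal protein genes 7.01 ± 0.30% and 7.46 ± 0.14% (exact p = 0.0857, adjusted 0.161, as for B cell markers).

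Genes close to Cyp1b1 on chromosome 17 changed more often than genes elsewhere. Within 20 Mb of its start, 50 of 117 tested genes passed (42.7%), against 4329 of 14310 elsewhere (30.3%). The odds ratio was 1.72 (95% interval 1.17 to 2.52, two-sided Fisher's exact test, p = 0.00455). At a fold of at least 2, a limit chosen after the data were seen, 16 of 117 passed against 561 of 14310, an odds ratio of 3.88 (2.12 to 6.67, Fisher's exact p = 1.65e-05). Examples chosen after their values were seen were Eif2ak2, the double-stranded RNA sensor PKR (78852564 to 78882573), which changed by -1.65, and Rasgrp3 (75435905 to 75529043), by -1.13. Tgif1, a TGF-beta corepressor at 70844205 to 70853546, fell from 44.3 ± 5.54 to 18.5 ± 0.84 CPM, and Emilin2, at 71252172 to 71311978, rose from 5.81 ± 0.89 to 64.7 ± 7.11 CPM (SD, n = 4 each). Of the 16 genes, 14 were lower and 2 higher in the libraries labelled knockout, and 15 lay at 70 to 80 Mb, before Cyp1b1, with 1 after it. Several overlap or adjoin each other, so they are not independent.

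**Figure D4:**
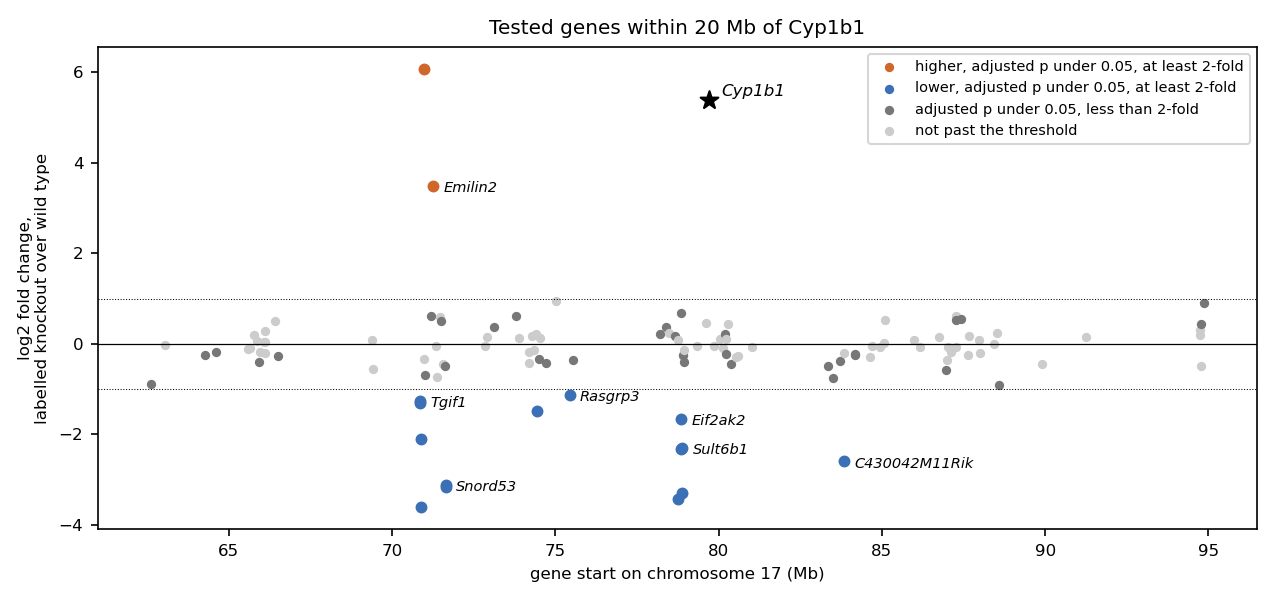
Log2 fold change (y axis, labelled knockout over labelled wild type) of the 117 tested genes within 20 Mb of Cyp1b1 by gene start on chromosome 17 (x axis, Mb), with Cyp1b1 as a star and dotted lines at 2-fold. Of the 16 genes changed by at least 2-fold, 15 lie before Cyp1b1 and 1 after it, and 14 are below 0.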

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

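Several tests in this part were chosen after the results were seen. They were those on genes 5 to 20 Mb from Cyp1b1, on the exchange of labels, on AhR activity and on residual B cells. The lists tested for residual B cells and for GC content and gene length were also picked after their results were seen.

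In each group of 4 libraries, a value was called far from the rest where its gap exceeded 0.829 of the group's range (Dixon's 95% value). Of 302 groups tested 9 passed, and chance alone marks about 1 in 20 groups, or 15.1 here. Wild type 2 had 8918342 total counts against 13937896 or more in the other wild type libraries, and 11.7 CPM of Rpl24 against 6.94 or less. Wild type 1 stood apart with 1.30% of counts in mitochondrially encoded protein genes (others 1.87% or more), 0.994 CPM of Cacna1c (others 2.72 or more) and 15.3 CPM of Gzma (others 13.8 or less). Wild type 4 had 8.80 CPM of Hlx (others 7.16 or less). Knockout 1 had 22079 genes with a count (others 22813 or more) and 51.6 CPM of Dlat (others 47.7 or less). Knockout 2 had 10.2 CPM of Cd79b (others 12.8 or more).

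The count of called genes was set against all 35 splits of the 8 libraries into 4 and 4. Only 1, the real one, gave 4380 genes or more, and the highest of the other 34 gave 0 by edgeR. At an unadjusted edgeR p under 0.05 the others gave 75 to 2101 genes, against 5900 in the real one. No other tool was run on these splits. Each of the other 34 mixed the labels within its groups, which adds the difference between labels to the spread. Counts of 0 were therefore likely beforehand, and the 35 splits cannot exclude chance or a culture difference that runs with the labels.

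Cyp1b1 was higher in all 4 libraries labelled knockout than in all 4 labelled wild type. The other 9 AhR targets had a median log2 fold change of 0.11 (SE 0.32), far under the 5.39 of Cyp1b1. Of these targets 4 rose, such as Cyp1a1 at 1.44, 1 fell, Gpr15 at -0.87, and 4 did not pass. The comparison assumes that all targets rise by about the same fold, which was not tested. It therefore cannot decide whether higher AhR activity was the whole cause. An exchange of the 2 group labels cannot be told apart from labels that are right: of genes changed by at least 2-fold, 14 of 16 within 20 Mb of Cyp1b1 were lower in the libraries labelled knockout against 328 of 561 elsewhere (odds ratio 4.96, 1.12 to 45.4, Fisher's exact p = 0.0201). By the criterion first set this odds ratio alone went against an exchange; a shift of the window's other 101 genes was added as a condition after the odds ratio was seen, because the test assumes that reads of another strain's segment map less well, and it was not met (median -0.052 against 0.0018 elsewhere, rank-sum test across genes, by normal approximation rather than exact, p = 0.345). Transcription of a disrupted allele, with reads over exons that remain, also stays open and was not tested, since counts per gene hold no exons.

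Called genes were over-represented around Cyp1b1. A flanking segment of another strain, left from the making of the allele, may account for part of this: the odds ratio within 20 Mb was 1.72 (1.17 to 2.52). This window held 50 of the 4380 genes, but the length of any such segment is not known, and the labels name no strain. Whether the targeted allele affected its close neighbours alone was not decided. Genes at 5 to 20 Mb kept an odds ratio of 3.29 (1.44 to 6.67) at a fold of at least 2, but for all called genes it was 1.27 (0.762 to 2.08). Most of the genes behind the 3.29 lie in 1 stretch, from Tgif1 (start 70844205) to Gm22858 (end 71641659). Fisher's test treats them as independent, so its interval need not hold. Of 224 10-Mb bins with at least 20 tested genes, 70 to 80 Mb of chromosome 17 held the highest share of genes called at a fold of at least 2, 15 of 53 (28.3%), and the next highest bin 16%, while 80 to 90 Mb held 1 of 41. Such genes cannot be assigned to loss of Cyp1b1 by these data.

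Stress response, glycolysis and proliferation genes were higher in the libraries labelled knockout, where B cell markers were lower. With the B cell marker level as a covariate the 3 lists kept at least 85.9% of their median log2 fold changes. Their camera adjusted p values were 4.56e-09 or less. These values cannot decide whether fewer residual B cells were the whole cause, because the covariate follows the fall of the markers poorly. It is the log2 sum over the markers, whose median log2 fold change was -0.86. Ighm, the most abundant, stood at 345.9 CPM in the libraries labelled wild type and 342.5 CPM in those labelled knockout. A trend on GC content and gene length, which explained 1.18% of the variance of log2 fold changes, left at least 94.9% of each median once subtracted. A difference by genotype remains a hypothesis, with its direction resting on the labels, and changes in culture or in the share of other cells that these markers do not follow were not tested.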

How the results depend on the processing

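Of the alternatives, the subsets of knockout libraries, the sample split as a term, the B cell marker level as a covariate and the fold limit near Cyp1b1 were chosen after the data were seen. The 4380 called genes became 3428 to 5062 over 20 alternatives, 3559 to 4679 with 1 library left out, 4145 with DESeq2 and 4331 with limma-voom, and none changed sign in the alternatives that tested it (4293 of them were tested with CPM of at least 1 in 4 libraries and 3957 with protein-coding genes alone). Cyp1b1 stayed called in all 20, with log2 fold changes from 4.99 to 5.68, and the odds ratio near Cyp1b1 in all 13, from 1.31 to 3.88. With library totals alone, 1745 genes were higher and 2689 lower. Whether replicate numbers pair the libraries was not settled. Correlations of same-numbered deviations were 0.0906, 0.0507, 0.0524 and 0.0543. Knockout 1 and 3 correlated best with their own number, and knockout 2 and 4 with another number. With the replicate block 4936 genes passed. Of 128 named called genes apart from Cyp1b1, 110 kept the call in every alternative, and of the 12 called lists 9 did so apart from the estimated correlation. Called lists (12, 7 higher, 5 lower) became 19 and 14 higher with no low-count filter, where more genes were tested, 1, 1 and 0 with an estimated correlation, and 21, 12 and 9 with fry, which does not compare a list with other genes; with 1 library left out they were 11 to 15, 6 to 9 and 4 to 6. Summed CPM of CD4 identity genes differed by 515.9 with TMM sizes and 180.7 with library totals. The direction of the fold change turned in 4 genes and that of the test in 8 lists, called neither in the main analysis nor in the fit that turned them, and the cause was not tested. Log2 fold changes with 1 library left out were -0.18 to 0.022 for Il17f, -0.045 to 0.10 for Foxp3, and with knockout 2 and 3 alone 0.069 and -0.13. With the B cell covariate Il17f kept its sign and was called, at -0.43 (adjusted p = 0.000628), and the Th17 core list was called there. With the replicate block the Th17 core, AhR target and cholesterol lists were called (0.0263, 0.0348 and 0.0477). Fry called as lower, where camera did not, pathogenic Th17 (0.0323), TGF-beta response (0.00454), apoptosis regulators (0.0389) and innate-like markers (0.012). It called as higher Th2 (0.000456), AhR targets (0.00224), cholesterol (0.0375), stromal markers (0.00234) and CD4 identity (0.0208). Foxp3 gave -0.021 with library totals, Csf2 -0.14 and Ahr -0.13 with the B cell covariate, and Ahr -0.021 with knockout 1 and 4 alone. For the 8 lists medians were as follows; a test can turn while the median keeps its sign, and medians also changed sign, with no turn of the test, in lists such as retinoid response (-0.037 with no low-count filter). With 1 library left out they were -0.062 to 0.15 for non-pathogenic Th17, -0.12 to -0.019 for Th1, -0.24 to 0.038 for mitochondrially encoded, 0.022 to 0.059 for TCA cycle, 0.0098 to 0.083 for fatty acid oxidation, and -0.19 to 0.33 for erythroid and platelet markers. With the B cell covariate Th1 gave -0.030, mitochondrial biogenesis 0.018, fatty acid oxidation 0.089 and myeloid markers 0.21. With knockout 2 and 3 alone mitochondrially encoded genes gave 0.12, TCA cycle 0.023 and fatty acid oxidation 0.048. With library totals TCA cycle and fatty acid oxidation gave 0.0028 and 0.0024, and with the sample split as a term mitochondrially encoded genes and fatty acid oxidation gave 0.10 and 0.038. Th1 gave -0.058 with knockout 1 and 4 alone and -0.059 with no low-count filter, where erythroid markers gave 0.93. Fatty acid oxidation gave 0.050 with CPM of at least 1 in 4 libraries and 0.053 with the replicate block, where myeloid markers gave -0.18. At this depth 68.7% of simulated 1.5-fold changes were recovered, in a simulation with far fewer changed genes than were called here.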

Other observations

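Other T helper programs were also mixed in the libraries labelled knockout, a label that the Cyp1b1 level goes against. Th2 genes had 4 higher and 3 lower of 9 members (4 and 3 adjusted over the list alone): Il4ra, the interleukin-4 receptor chain, rose from 832.1 ± 32.6 to 1474 ± 157.4 CPM and Gata3, the Th2 factor, from 19.6 ± 1.54 to 31.9 ± 0.92 CPM (SD, n = 4 each), while Il1rl1 had a log2 fold change of -1.41. Th1 genes had 5 higher and 3 lower of 14 (5 and 5), with Hlx at 1.12 and the interleukin-18 receptor gene Il18r1 at -0.91. Regulatory T cell genes had 3 higher and 6 lower of 17 (3 and 6), with the folate receptor gene Izumo1r and Gpr83 at 0.87 and 1.58 and Tigit at -0.77. Naive T cell genes had 4 and 3 of 18 (5 and 3), with Igfbp4 at 0.44 and Btg1 at -0.45. None of the 4 lists was called by camera, with medians of 0.20, -0.10, -0.11 and 0.11 and adjusted p values of 0.145, 0.825, 0.355 and 0.693, or 0.351, 0.888, 0.673 and 0.888 with an estimated correlation. With no low-count filter the Th2 list passed as higher (median 0.49, adjusted p = 0.00423), as it did with fry (adjusted p = 0.000456).

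Signalling and metabolic lists outside the report's groups were not called either. Interferon-stimulated genes had 7 higher and 5 lower of 25 (7 and 5 adjusted over the list alone), and in them the GTPase gene Gbp2 rose from 367.0 ± 49.4 to 1184.5 ± 87.0 CPM (SD, n = 4 each) and the nucleic acid sensor Zbp1 by 0.99 on the log2 scale. Cholesterol synthesis genes had 11 and 2 of 24 (11 and 2), with Mvk at 0.70. TGF-beta response genes had 4 and 3 of 15 (5 and 4), with Skil at -0.67, and retinoid response genes 4 and 1 of 9 (5 and 2), with Tgm2 at 0.49, which did not pass with knockout 1 and 4 alone (adjusted p = 0.144) or 2 and 3 alone (0.101). Unfolded protein response genes had 6 and 0 of 19 (6 and 0), with Herpud1 at 0.42. Apoptosis regulators had 4 and 5 of 22 (4 and 5), and Bcl2l11, the gene of the death inducer BIM, fell from 249.6 to 146.0 CPM (n = 4 each). Migration and integrin genes had 4 and 6 of 21 (5 and 7), with Cxcr5 at -0.93, and immediate early genes 3 and 5 of 16 (3 and 6), with Atf3 at 0.92 and Zfp36 at -0.55. Camera adjusted p values of these 8 lists were 0.178, 0.0516, 0.355, 0.561, 0.23, 0.355, 0.178 and 0.594, and 0.624 or more with an estimated correlation. The unfolded protein response list passed as higher with no low-count filter (0.0114). The interferon list passed as higher without wild type 4 (0.02), with no low-count filter (0.0371) and with the B cell covariate (0.00525). The cholesterol list passed as higher without wild type 4, knockout 2 or knockout 3 (0.0276, 0.0165 and 0.0193), with no low-count filter (0.00011), with knockout 1 and 4 alone (0.00111) and with the B cell covariate (0.00586).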
